A study of Arabidopsis thaliana with 4 samples.

How the data were processed

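Total RNA from roots of 3-week-old seedlings of the *Arabidopsis thaliana* accession Col-0 was measured on ATH1 Affymetrix expression arrays, on which a probe set is a group of short probes that reads out a transcript near its 3' end. The 4 arrays fall into 2 groups of 2 by the labels: roots of mock-treated seedlings, and roots of seedlings kept in hydroponic culture for 8 h with *Agrobacterium tumefaciens* strain C58. The title and source fields set the groups, since the description and protocol fields are worded alike for all 4 samples and speak of the bacterium for the mock samples too. The labels number the arrays of each group 1 and 2 as biological replicates, and do not say whether a number stands for plants, vessels or days. The p-values rest on the spread between these arrays, drawn toward the spread of all probe sets. Which sources of variation that spread covers is not known.

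The deposited values are log2 expression values, 1 per probe set and array, and the authors made them with RMA (background correction, normalization and summary of the probes of a probe set), per the submitters' processing notes. The version, the probe definition and the settings of RMA are not given in the sources used here, and neither is whether all 4 arrays were normalized together. The log2 unit was read from the values themselves, which run from 2.92 to 13.8 over all arrays with 0 missing values on each. The scanner intensities were not used here, so no call of presence or absence above background was made, and low values were tested like the others. RMA values compress changes of dim probe sets, so a fold change of a gene near the bottom of the range is understated.

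The table holds 22810 probe sets. The 64 control probe sets were left out, and 22746 were tested. Gene names came from a platform annotation table, matched by gene identifier to the RefSeq gene table of assembly TAIR10.1, which was used for names only. Of the tested probe sets, 13513 named 1 gene, 503 named several and 8730 were unnamed here, which does not mean that they lack a gene. The identifiers of 13436 single-gene probe sets were found in the RefSeq table, and 77 kept the symbol of the platform table. For gene-level results each of 13356 genes was represented by its single-gene probe set with the highest mean over the 4 arrays, a choice that mattered for the 146 genes with more than 1. No reference genome was used, and no coordinates are given.

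Differences between inoculated and mock roots were tested with limma version 3.58.1 in R version 4.3.3, with a linear model per probe set and moderated standard errors (lmFit and eBayes, default settings, two-sided). Adjusted p is by Benjamini-Hochberg over the 22746 probe sets, with a threshold of 0.05. The fit had 2 residual and 4.58 prior degrees of freedom. Every ± beside a log2 change is the model's standard error (SE), and every ± beside a group mean is the SD of 2 arrays. The number of arrays limits the precision, and the median SE of a log2 change was 0.11. Pathway and cell type lists were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Counts of list members are given over all probe sets and adjusted over the list alone.

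The 29 gene lists, with 698 members in all, the tests and the rule for naming genes were fixed before the data were examined. The rule took the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose groups did not overlap. It added the 2 members of each list with the largest moderated t in size (3 for lists past the camera threshold), and 6 markers whatever their test. In all, 72 genes were named by the rule. Only 111 list members had a single-gene probe set named here, and 3 others lay on probe sets that name several genes. The lists therefore rest on few genes: 17 had 3 or more measured members, 2 had none, and many widely used marker genes are among the unmeasured ones.

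The fit was tested on simulated arrays with the real means and limma's fitted spread, in which 200 of the 22746 probe sets were changed by a known amount. A change of 0.5 on the log2 scale was recovered for 0% of them, a change of 1 for 84.5% with 11 false calls, and a change of 2 for 100% with 9 false calls. With so few changed probe sets the adjusted threshold is stricter than on the real arrays, where 6218 probe sets passed. The 0% at 0.5 therefore does not describe recovery on the real arrays. In a simulation in which the 7 hypoxia genes were shifted by 1, camera called that list and 0 of 26 others. Its genes were drawn independently, and no gene outside the hypoxia list was changed. It therefore does not show how often camera calls unshifted lists on the real arrays.

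The alternatives were a filter at the median level, repeated quantile normalization, median centring, an intensity trend with robust moderation, the replicate number as a block, leaving out each array in turn, a plain t statistic, camera with an estimated correlation, fry, and, for the gene lists only, the mean of all probe sets of a gene. A minimum of 3 measured genes per list was added after the data were seen. So were 41 gene families formed from the shared start of gene symbols, with at least 6 genes each, and 2 lists written from gene identifiers (class III peroxidases and small heat shock proteins).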

Results

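The data are log2 expression values from 4 ATH1 arrays of Col-0 roots, 2 mock-treated and 2 co-cultivated for 8 h with *Agrobacterium tumefaciens* C58, a soil bacterium that transfers DNA into plant cells and causes crown gall. The array medians were 6.25 and 6.28 in the mock group and 6.21 and 6.24 in the inoculated group. Probe set by probe set, the arrays of one group resembled each other more than arrays of different groups. Across probe sets, which are not independent replicates, Pearson's r was 0.996 between both mock arrays and 0.996 between both inoculated arrays, against 0.966 to 0.968 between groups. The median absolute difference was 0.12 within each group and 0.21 to 0.25 between groups. The distributions of values instead followed the replicate number. The mean absolute difference of sorted values was 0.024 between both arrays numbered 1 and 0.027 between both numbered 2. Within groups it was 0.063 (mock) and 0.069 (inoculated).

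The comparison of inoculated with mock roots asks which root transcripts respond to the bacterium within 8 h. Among the measured genes of the fixed lists, 3 of 3 heat shock genes (19 in the list) and 5 of 6 detoxification genes (30 in the list) were higher after inoculation. Of 11 tau-class glutathione transferase genes, a family formed after the data were seen, 2 were higher and 5 lower. In the other fixed lists, 8 of 12 measured expansin and XTH genes (32 in the list) were lower. So were 4 of 5 root hair markers (19 in the list) and 3 of 3 cell cycle genes (26 in the list). Of the photosynthesis genes, used as markers of shoot tissue, 3 of 4 were lower (30 in the list). Among the 13356 genes with a named single-gene probe set, the largest rise was that of AT1G05340. It went from 7.43 ± 0.10 to 12.10 ± 0.00 (SD, n = 2 arrays), a log2 change of 4.67 ± 0.10 (SE) or 25.4-fold (limma, adjusted p = 7.61e-06). AT2G43590 was close behind at 4.59 ± 0.10. Among the same genes the largest fall was that of AT3G19430, from 9.29 ± 0.08 to 5.08 ± 0.02, a log2 change of -4.21 ± 0.10 (adjusted p = 7.61e-06). AT3G01190 was close at -4.19 ± 0.12. The 8730 unnamed probe sets were not ranked, and 2785 of them were past the threshold. In all, 6218 of 22746 probe sets (27.3%) passed, 2889 higher and 3329 lower, and 1311 of them changed at least 2-fold, 696 higher and 615 lower. Of 13356 genes, 1499 were higher and 1804 lower.

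In each of the 6218 passing probe sets the 2 groups did not overlap. Over all probe sets 59.9% did not overlap, where chance gives 33.3%. The count of passing probe sets fell to 4027 without mock replicate 2, and a plain t statistic without moderation passed 46 after adjustment. With median centring the balance turned, to 3213 higher and 2900 lower. These numbers rest on 2 arrays per group.

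**Figure D1:**
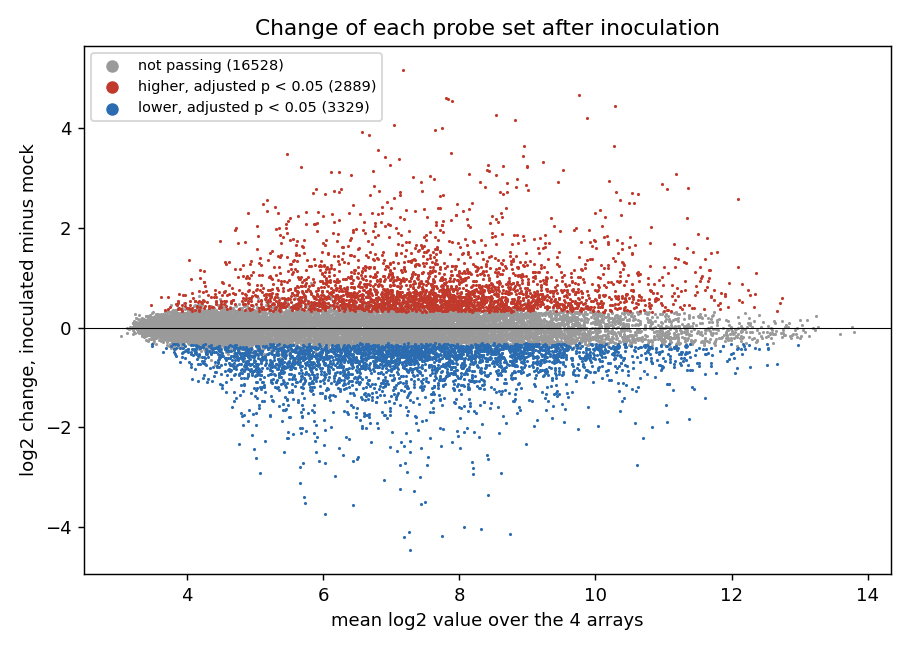
Log2 change of each of the 22746 probe sets (inoculated minus mock) against its mean log2 value over the 4 arrays, with passing probe sets in red (2889 higher) and blue (3329 lower) and the others in grey. Changes in both directions span the range of expression levels.

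Among the 8 largest rises, 3 genes encode chaperone-type proteins. The small heat shock protein gene AT1G52560 rose by 4.55 ± 0.11 (SE, log2), HSP15.7 (AT5G37670), a small heat shock protein, by 4.07 ± 0.10, and AT1G71000, which encodes a DnaJ-domain protein, by 3.87 ± 0.13. AT2G43590, a member of the chitinase family, rose from 5.51 ± 0.09 to 10.11 ± 0.05 (SD, n = 2 arrays), or 24.1-fold. GH3.3 (AT2G23170), which conjugates auxin to amino acids, rose 15.3-fold, from 4.60 ± 0.19 to 8.53 ± 0.16. The methyltransferase gene AT2G41380 rose by 4.27 ± 0.11, and AT4G28460, a gene for a small secreted peptide precursor, by 3.39 ± 0.14. Adjusted p for these genes lay between 7.61e-06 and 3.4e-05.

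Among the 8 largest falls, AT3G01190, a class III peroxidase, fell from 9.84 ± 0.02 to 5.65 ± 0.18 (SD, n = 2 arrays). The SKU5-similar gene sks15 (AT4G37160) fell from 7.90 ± 0.16 to 4.16 ± 0.03, and AT5G62340, of the pectin methylesterase inhibitor family, from 7.41 ± 0.18 to 4.01 ± 0.05. AT5G10130, of the Ole e 1 family, had a log2 change of -3.53 ± 0.11 (SE), and AT1G50060, of the CAP family of secreted proteins that includes PR1, one of -3.52 ± 0.19. For AT5G60520 the log2 change was -4.09 ± 0.11, and for AT5G57785 -3.55 ± 0.12. The highest adjusted p of the 8 was 7.71e-05.

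**Figure D2:**
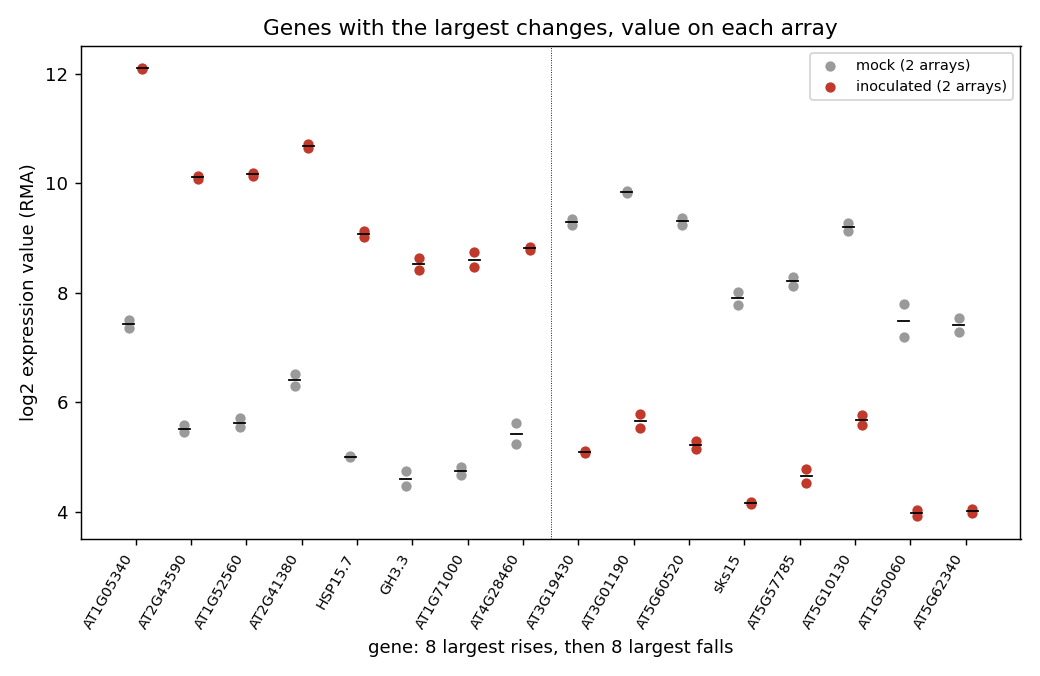
Log2 expression value (RMA) on each array for the 8 genes with the largest rise and the 8 with the largest fall among the 13356 genes. Grey points are the 2 mock arrays, red points the 2 inoculated arrays, and black lines the group means. AT1G05340 lies near 7.43 on the mock arrays and 12.10 on the inoculated arrays, and the groups are apart for each of the 16 genes.

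Of the 29 gene lists, 27 had a measured member and 10 passed camera's threshold, 5 higher and 5 lower. With an estimated correlation 0 of the 22 lists with more than 1 gene passed (limma camera; also 0 at an unadjusted p under 0.05), while fry, which asks whether a list's genes move one way on balance without comparing them with other genes, passed 18. Adjusted p with an estimated correlation was 0.463 for the heat shock, detoxification, hypoxia, salicylic acid, expansin, cell cycle, root hair and photosynthesis lists. It was 0.467 for the phenylpropanoid and suberin lists. The shared 0.463 comes from the adjustment: the unadjusted camera p ran from 0.0515 for heat shock to 0.168 for root hair markers. That version of camera rests on the 2 residual degrees of freedom, so short lists could hardly pass it. The detoxification list had an estimated correlation of 0.0095, near the preset 0.01, yet its unadjusted p was 0.0668 against 0.000245. Losing the call there does not show that correlation between genes explains a shift. When only probe sets at or above the median level were kept, 1 list passed, heat shock. Of 4 shoot markers, given with the falling lists, 3 were themselves lower in the inoculated roots.

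The 3 measured genes of the heat shock list, which encode small heat shock proteins, were all higher (median 2.79, camera adjusted p = 0.000743; 3 adjusted over the list alone). HSP17.6C (AT1G53540) rose from 9.96 ± 0.05 to 12.75 ± 0.06 (SD, n = 2 arrays), and HSP22.0 (AT4G10250) from 10.81 ± 0.23 to 11.50 ± 0.03. Of 6 measured glutathione transferase and detoxification genes, 5 were higher and 1 lower, both over all probe sets and adjusted over the list alone (median 1.40, camera adjusted p = 0.00221). GSTU25 (AT1G17180), a tau-class glutathione transferase, rose by 3.06 ± 0.15 (SE, log2), and the glycosyltransferase gene UGT73B4 (AT2G15490) by 2.93 ± 0.12. GSTU20 (AT1G78370), of the same class as GSTU25, went the other way, from 9.30 ± 0.14 to 7.37 ± 0.10. In families formed after the data were seen, 2 of 11 tau-class genes were higher and 5 lower. Of 47 genes with UGT symbols, 11 were higher and 11 lower. For the heat shock and detoxification lists the camera adjusted p with an estimated correlation was 0.463. A temperature difference between culture vessels was not tested, and the labels do not give the temperature of each vessel.

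Of 7 measured hypoxia genes, 4 were higher and 1 lower, or 5 higher and 1 lower adjusted over the list alone (median 0.63, camera adjusted p = 0.0362, adjusted p = 0.463 with an estimated correlation). HUP26 (AT3G10020) rose 6.4-fold and HUP9 (AT5G10040) 1.9-fold, while HRA1 (AT3G10040), a transcription factor that restrains the hypoxia response, went from 8.52 ± 0.08 to 6.98 ± 0.02 (SD, n = 2 arrays). The alcohol dehydrogenase gene ADH1 had no single-gene probe set named here, so its change is unknown. The list's camera adjusted p was 0.0795 without mock replicate 1 and 0.0582 without inoculated replicate 2.

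In the phenylpropanoid and lignin list 2 of 3 measured genes were higher, also adjusted over the list alone (median 0.54, camera adjusted p = 0.0362, adjusted p = 0.467 with an estimated correlation). F6'H1 (AT3G13610), which makes the precursor of the coumarin scopoletin, rose from 9.79 ± 0.10 to 11.29 ± 0.02 (SD, n = 2 arrays). The cinnamoyl-CoA reductase gene CCR2 (AT1G80820) rose by 0.54 ± 0.13 (SE, log2; adjusted p = 0.0251), and HCT (AT5G48930) differed by 0.16 ± 0.11, which did not pass (adjusted p = 0.342). The adjusted p of CCR2 was 0.111 without mock replicate 1, 0.0542 without inoculated replicate 1 and 0.103 without inoculated replicate 2. The list's camera adjusted p was 0.0795 without mock replicate 1 and 0.0861 without inoculated replicate 2.

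In the salicylic acid list, which had 2 measured genes, both were higher, also adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.463 with an estimated correlation). The glutaredoxin gene GRX480 (AT1G28480) rose 3.34-fold, and SAG101 (AT5G14930), an EDS1 partner in immunity, by 0.47 ± 0.13 (SE, log2; adjusted p = 0.0355). Without mock replicate 1 the adjusted p was 0.163 for SAG101 and 0.0795 for the list. Without inoculated replicate 2 these were 0.159 and 0.0599. The list also missed the threshold with median centring (adjusted p = 0.0517) and with the trend and robust moderation (0.0506), over a range of 0.0289 to 0.0795 with 1 array left out.

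Of 12 measured expansin and XTH genes, which act in wall loosening, 8 were lower and 1 higher, also adjusted over the list alone (median -0.77, camera adjusted p = 0.00158, adjusted p = 0.463 with an estimated correlation). EXPB3 (AT4G28250) went from 10.27 ± 0.11 to 8.46 ± 0.02 (SD, n = 2 arrays), and XTH21 (AT2G18800), a xyloglucan-modifying enzyme gene, from 5.87 ± 0.00 to 4.16 ± 0.15. EXPB1 (AT2G20750) went from 6.19 ± 0.10 to 4.74 ± 0.00. The single higher member, XTH18, rose by 1.33 ± 0.10 (SE, log2) and was named after its values were seen. On the same arrays 3 of 4 shoot markers were lower, with a median log2 change of -0.64.

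Of 5 measured root hair markers, 4 were lower, also adjusted over the list alone (median -1.71, camera adjusted p = 0.00341, adjusted p = 0.463 with an estimated correlation). PER7 (AT1G30870), a peroxidase gene, went from 8.50 ± 0.06 to 5.75 ± 0.24 (SD, n = 2 arrays). The root hair expansin genes EXPA18 (AT1G62980) and EXPA7 (AT1G12560) had log2 changes of -2.22 ± 0.10 and -1.71 ± 0.15 (SE), to levels of 4.36 and 4.92 near the bottom of the range. The 3 measured cell cycle genes were all lower, also adjusted over the list alone (median -1.12, camera adjusted p = 0.00341, adjusted p = 0.463 with an estimated correlation). MCM7 (AT4G02060), part of the replicative helicase, had a log2 change of -1.16 ± 0.13, and the mitotic Aurora kinase gene AUR1 (AT4G32830) -1.12 ± 0.10. Its relative AUR2 (AT2G25880) went from 7.62 ± 0.16 to 6.62 ± 0.07 (SD). Beside both lists, the shoot markers had a median log2 change of -0.64.

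Of 4 measured photosynthesis genes, used as markers of shoot tissue, 3 were lower, or 4 adjusted over the list alone (median -0.64, camera adjusted p = 0.021, adjusted p = 0.463 with an estimated correlation). RCA (AT2G39730), Rubisco activase, went from 9.30 ± 0.14 to 8.58 ± 0.01 (SD, n = 2 arrays). LHCB4.1 (AT5G01530), a light-harvesting protein gene, and PRK (AT1G32060), phosphoribulokinase, had log2 changes of -0.56 ± 0.11 and -0.73 ± 0.18 (SE). Without mock replicate 2 the adjusted p was 0.063 for LHCB4.1 and 0.116 for PRK, and without inoculated replicate 1 it was 0.058 and 0.0862. In the suberin and Casparian strip list 1 of 2 measured genes was lower, or 2 adjusted over the list alone (median -1.09, camera adjusted p = 0.0446, adjusted p = 0.467 with an estimated correlation). SGN1 (AT1G61590), a kinase needed for the Casparian strip, went from 7.48 ± 0.21 to 5.62 ± 0.16, and SGN3 (AT4G20140), a receptor kinase of the same pathway, differed by -0.31 ± 0.09 (adjusted p = 0.052, but 0.0161 with the level filter and 0.0344 with repeated quantile normalization). The suberin list's camera adjusted p was 0.0524 to 0.0688 with any of the 4 arrays left out, 0.0506 with the trend and robust moderation and 0.154 with the level filter.

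**Figure D3:**
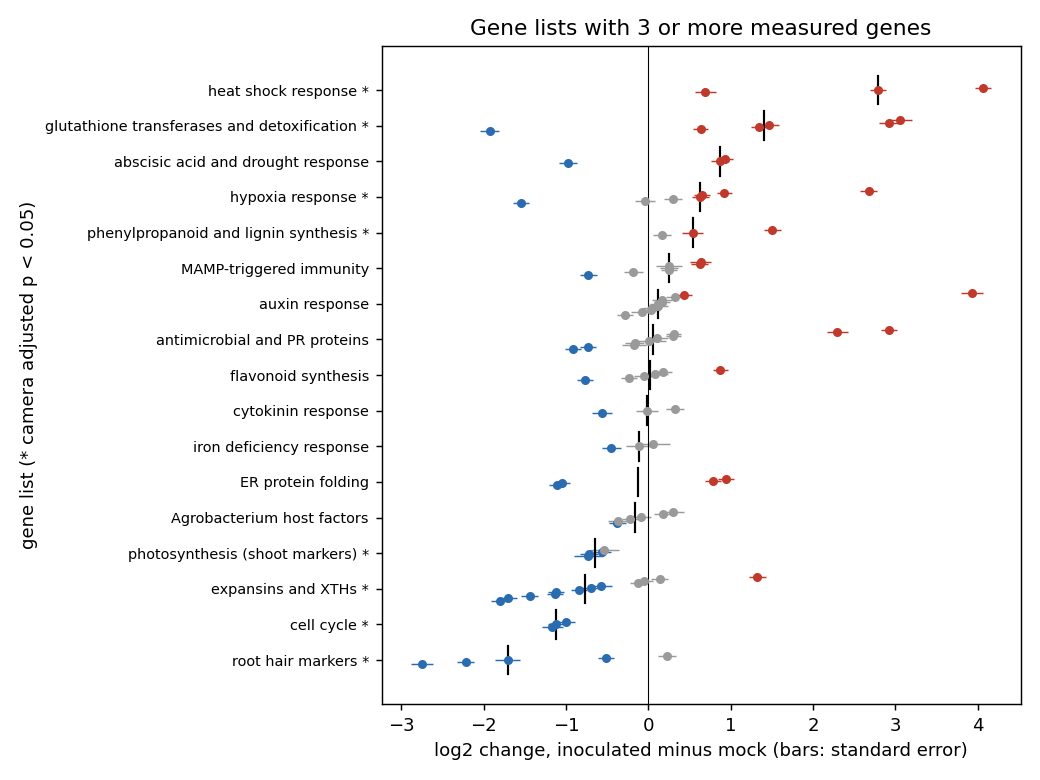
Log2 change (inoculated minus mock) of each measured member of the 17 lists with 3 or more measured genes. Points are genes with their SE, red and blue where adjusted p passed 0.05 and grey otherwise, black lines are list medians and stars mark lists past camera's threshold; the medians run from -1.71 for root hair markers to 2.79 for heat shock.

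The immune lists beyond salicylic acid moved in mixed ways. Of 7 measured genes of MAMP-triggered immunity, the response to conserved microbial molecules, 2 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.305). The ubiquitin ligase gene PUB24 (AT3G11840) rose by 0.62 ± 0.10 (SE, log2), and the transcription factor gene WRKY53 (AT4G23810) had a change of -0.73 ± 0.10. Of 10 measured antimicrobial and PR genes, 2 were higher and 2 lower, or 4 and 2 adjusted over the list alone (median 0.06, mean 0.40, camera adjusted p = 0.449). The peroxidase genes PER71 (AT5G64120) and PER62 (AT5G39580) rose 7.58-fold and 4.91-fold (adjusted p = 1.59e-05 and 6.86e-05). The defensin gene PDF1.2 (AT5G44420), a marker of jasmonate and ethylene defence, differed by 0.01 ± 0.20 at a level of 4.18 ± 0.45 (SD, n = 2 arrays) in mock roots (adjusted p = 0.992). The other 5 markers fixed in advance, PR1, VSP2, FRK1, CYP71A12 and ADH1, had no single-gene probe set named here, so their changes are unknown.

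FOX1 (AT1G26380), an oxidase gene of the indole-derived defence pathway, rose 9.3-fold, from 4.07 ± 0.30 to 7.29 ± 0.11 (SD, n = 2 arrays). The other measured gene of the camalexin and indole glucosinolate list, UGT74B1 (AT1G24100), differed by -0.02 ± 0.10 (SE, log2), so 1 of 2 was higher, also adjusted over the list alone (camera adjusted p = 0.15). The tryptophan pathway gene IGPS (AT2G04400) was the single measured member of its list and rose by 0.60 ± 0.10, also adjusted over the list alone (camera adjusted p = 0.15). Of 6 flavonoid genes, 1 was higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.952). These were both glycosyltransferase genes, UGT78D2 (AT5G17050) at 0.88 ± 0.10 and UGT78D1 (AT1G30530) at -0.77 ± 0.10.

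Hormone lists other than salicylic acid did not pass. Of 11 measured auxin genes, 2 were higher, also adjusted over the list alone (camera adjusted p = 0.0944): GH3.3 and LBD16 (AT2G42430), a lateral root transcription factor gene, at 0.43 ± 0.10 (SE, log2; adjusted p = 0.0185). LBD16 missed the threshold with any of the 4 arrays left out, mock replicate 1 or 2 or inoculated replicate 1 or 2 (adjusted p 0.0516 to 0.0983). In the ethylene list 1 of 2 measured genes was higher, or 2 adjusted over the list alone (camera adjusted p = 0.0692, and 0.0371 without mock replicate 2). RTE1 (AT2G26070), a regulator of the ethylene receptor ETR1, rose by 0.77 ± 0.10, and EIN3 (AT3G20770) differed by 0.36 ± 0.12 (adjusted p = 0.0655). EIN3 passed with the level filter (adjusted p = 0.0243), repeated quantile normalization (0.0498), median centring (0.041) and the trend and robust moderation (0.0159).

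Of 3 cytokinin genes, 1 was lower, or 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.937). UGT76C2 (AT5G05860), which glucosylates cytokinins, had a log2 change of -0.56 ± 0.12 (SE; adjusted p = 0.0134, 0.0714 without mock replicate 2 and 0.0619 without inoculated replicate 1), and ARR16 (AT2G40670) differed by 0.33 ± 0.11 (adjusted p = 0.0718, and 0.0497 with median centring). Of 3 abscisic acid and drought genes, 2 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.358). The dehydrin gene XERO2 (AT3G50970) rose by 0.94 ± 0.09, and the cold-regulated gene COR15A (AT2G42540) had a change of -0.97 ± 0.11. The single measured jasmonate gene, OPCL1 (AT1G20510), differed by 0.05 ± 0.17, and 0 members passed adjusted over the list alone (camera adjusted p = 0.937).

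All 4 measured genes of protein folding in the endoplasmic reticulum passed, 2 higher and 2 lower, also adjusted over the list alone (median -0.13, camera adjusted p = 0.937). The chaperone genes CRT2 (AT1G09210), a calreticulin, and ERDJ3B (AT3G62600) had log2 changes of -1.11 ± 0.09 and -1.05 ± 0.09 (SE). The transcription factor genes BZIP60 and BZIP28, which activate the unfolded protein response and were named after their values were seen, rose by 0.94 ± 0.09 and 0.78 ± 0.10.

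Of 6 measured plant genes known as host factors of *Agrobacterium* transformation, 1 was lower, and 0 adjusted over the list alone (camera adjusted p = 0.579). RTNLB8 (AT3G10260), a reticulon-like protein gene, had a log2 change of -0.38 ± 0.10 (SE; adjusted p = 0.0358), and its adjusted p was 0.0502 with median centring and 0.0559 to 0.176 with any of the 4 arrays left out, mock replicate 1 or 2 or inoculated replicate 1 or 2. TEB (AT4G32700), DNA polymerase theta, differed by -0.37 ± 0.12 (adjusted p = 0.0678, and 0.0439 without mock replicate 2).

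Among the remaining lists, the sugar transporter gene SWEET11 (AT3G48740), the single measured phloem marker, went from 7.32 ± 0.04 to 5.99 ± 0.10 (SD, n = 2 arrays), also passing adjusted over the list alone (camera adjusted p = 0.0658). Both measured xylem markers, IRX15 (AT3G50220) at -0.11 ± 0.12 (SE, log2) and IRX10 (AT1G27440) at 0.04 ± 0.14, did not pass, with 0 adjusted over the list alone (camera adjusted p = 0.937). Of 3 iron deficiency genes, 1 was lower, also adjusted over the list alone (camera adjusted p = 0.53). This was PYE (AT3G47640) at -0.45 ± 0.11 (adjusted p = 0.0292, but 0.0696 without mock replicate 1, 0.136 without mock replicate 2 and 0.147 without inoculated replicate 1). BHLH101 (AT5G04150) differed by -0.12 ± 0.15. The nitrate transporter gene NRT2.5 (AT1G12940) differed by 0.16 ± 0.18, with 0 passing adjusted over the list alone (camera adjusted p = 0.81). The clock gene GI (AT1G22770) rose by 0.37 ± 0.11 (adjusted p = 0.0488), also adjusted over the list alone (camera adjusted p = 0.33), and missed the threshold with any of the 4 arrays left out, mock replicate 1 or 2 or inoculated replicate 1 or 2 (adjusted p 0.0605 to 0.225). The phosphate starvation and aquaporin lists had 0 measured members.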

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

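Both tests in this part were chosen after the values had been seen. The control probe sets lie outside the comparison of the report, and among 19 of them that read plant transcripts 4 were higher in the inoculated arrays, past the threshold (limma, adjusted over the 64 control probe sets) and above both mock arrays. All 4 read ubiquitin transcripts. The log2 changes were 0.43 and 0.51 for the 3' probe sets of the older and the newer design, 0.50 for the older 5' probe set and 0.72 for its middle probe set. The 5 ubiquitin probe sets together had a median of 0.50, and 0.49 and 0.54 with repeated quantile normalization and median centring. The rise was not confined to ubiquitin. Each GAPDH control probe set was above both mock arrays on both inoculated arrays, by a mean of 0.17 to 0.37. None of these passed (limma, lowest adjusted p = 0.0716). The actin control probe sets changed by -0.11 to -0.01. A difference in RNA integrity would shift the 5' ends against the 3' ends. The 3' minus 5' difference changed by -0.13 to 0.11 over 6 pairs of probe sets, which read actin, GAPDH and ubiquitin in both designs. The lowest change of the 5' ubiquitin probe sets was 0.41 ± 0.10 (SE, limma adjusted p = 0.0678), which by itself does not bear on integrity. A scaling that lifts the inoculated arrays would lift the hybridization spikes too, and their median change was -0.10 over 18 probe sets. The deposited values were already normalized, with a median change of -0.0012 over all probe sets. Little room was left for such a lift, so the spikes add little. The 3' minus 5' differences argue against a difference in RNA integrity, for the transcripts they cover. A higher level of ubiquitin transcripts after inoculation stays open as a hypothesis, since cross-hybridization within the ubiquitin family and differences between vessels were not tested.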

How the results depend on the processing

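A minimum of 3 measured genes per list was tried after the data were seen and passed 8 lists; the other alternatives were fixed in advance. The count of 6218 passing probe sets was 5903 with the level filter, 6920 with repeated quantile normalization, 6113 with median centring and 7040 with trend and robust moderation. It was 4027 to 4408 with 1 array left out, where the lone array is assumed to vary like the other group, and 4027 was the value without mock replicate 2. A plain t statistic without moderation passed 46, against 6253 at an unadjusted p under 0.05, which follows from a spread estimated with 2 degrees of freedom. In each of these fits except the plain t, 0 probe sets shared with the 6218 changed sign. That was close to fixed in advance, since only probe sets past the threshold in both fits were counted. The level filter and the trend and robust moderation also leave each log2 change as it was. The count of at least 2-fold changes was 956 to 1317 over the alternatives with 4 arrays and 1310 to 1390 with 1 array left out. The 10 passing lists became 1 with the level filter, 0 with an estimated correlation, 18 with fry and 6 to 10 with 1 array left out, with 6 both without mock replicate 1 and without inoculated replicate 2. It was 10 with the mean of all probe sets of a gene and 8 to 10 under the other alternatives with 4 arrays. The cause was not tested for the filter and the left-out arrays; an estimated correlation from 2 residual degrees of freedom and fry's different question are part of those tests' construction. Of 629 values of the 72 named genes under alternatives, 592 kept their side of the threshold, 27 lost the call and 10 gained one. The sign differed in 12 of the 592, from 7 genes that passed neither in the main fit nor there; genes below the median level, and with them the salicylic acid list, have no value under the filter. Without scanner intensities the signal over background is unknown, so calls on dim probe sets carry an error these arrays do not show.

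With the replicate number as a block, 7470 probe sets and 10 lists passed, and so did EIN3 (adjusted p = 0.0346) and SGN3 (0.0364). Same-numbered arrays deviated together across probe sets (r = 0.381, and 0.291 after repeated quantile normalization), but 2 pairs do not establish that the numbers pair the samples.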

Other observations

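The families, the 2 added lists and the tests of explanations in this part were chosen after the values had been seen, while the root hair and shoot marker lists were fixed in advance. Among 43 such groups, 4 passed camera, and 0 passed with an estimated correlation (limma camera, with 1 at an unadjusted p under 0.05). That version again rests on the 2 residual degrees of freedom and could hardly pass a group. By fry 4 groups passed: small heat shock proteins (adjusted p = 0.000845), and alpha-expansins, class III peroxidases and the family with TBL symbols (0.0484 each). The ATG genes (0.0907) and the serine carboxypeptidase-like genes (0.0805), which passed camera, did not. All 8 measured small heat shock protein genes were higher (median 2.08, camera adjusted p = 1.92e-09, adjusted p = 0.896 with an estimated correlation), also with both other scalings. A temperature difference between culture vessels was not tested. The small heat shock genes included HSP17.4III at 3.33 ± 0.12 (SE, log2) and HSP23.5 at 1.25 ± 0.09. They also included AT1G52560 and HSP15.7 of the 8 largest rises, and HSP17.6C and HSP22.0 of the heat shock list. The test of this added list therefore partly restates those rises. Of 8 autophagy genes with ATG symbols, 4 were higher and 0 lower (5 and 0 with median centring; median 0.55, camera adjusted p = 0.00166, adjusted p = 0.913 with an estimated correlation). Of the 8, 7 encode ATG8, the protein that is coupled to autophagosome membranes, and 4 of these passed: ATG8E at 2.27 ± 0.23, ATG8H at 2.26 ± 0.15, ATG8B at 1.04 ± 0.13 and ATG8F at 0.74 ± 0.11. ATG8G, ATG8D and ATG8C differed by 0.35 ± 0.11, 0.31 ± 0.13 and 0.26 ± 0.13 and did not pass, nor did ATG3 at 0.05 ± 0.11.

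Of 10 alpha-expansin genes, 6 were lower, or 5 with median centring (camera adjusted p = 0.00178, adjusted p = 0.913 with an estimated correlation), the largest fall being that of EXPA9 at -2.29 ± 0.18 (SE, log2). The 6 include EXPA7 and EXPA18 of the root hair list, and EXPA4 and EXPA15 of the expansin and XTH list. The test of this family therefore partly restates those falls. On the same arrays 4 of 5 root hair markers and 3 of 4 shoot markers were lower (medians -1.71 and -0.64, camera adjusted p = 0.463 with an estimated correlation for both). Of 29 serine carboxypeptidase-like genes, 9 were lower and 0 higher, with 11 and 1 under repeated quantile normalization and 7 and 1 under median centring (camera adjusted p = 0.0442, adjusted p = 0.913 with an estimated correlation). Tau-class glutathione transferase genes split, with 2 of 11 higher and 5 lower under all 3 scalings (camera adjusted p = 0.607). GSTU25 rose by 3.06 ± 0.15 and GSTU22 by 0.64 ± 0.09, and GSTU26 had a change of -1.79 ± 0.17. GSTU27 went from a mean level of 9.92 to 8.91. The isocitrate lyase gene ICL, of the glyoxylate cycle, rose by 2.98 ± 0.10, and the calmodulin-like gene CML37 by 2.23 ± 0.14.

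Class III peroxidases changed in both directions: of 55 measured genes, 12 were higher and 20 lower (12 and 21 with repeated quantile normalization, 12 and 19 with median centring; camera adjusted p = 0.313). PER71 rose by 2.92 ± 0.09 (SE, log2), while PER27, PER7 and PER35 had changes of -4.19 ± 0.12, -2.75 ± 0.13 and -2.50 ± 0.11. PER7 is also a root hair marker, and 4 of 5 of these were lower on the same arrays (median -1.71, adjusted p = 0.463 with an estimated correlation). PER27 is AT3G01190, given above among the largest falls, and PER71 and PER62 were named above from the antimicrobial and PR list. The count for this added list therefore partly restates those changes. The share of changed genes was 58.2%, against 24.7% of all genes. Brightness of the probe sets is argued against: among 10000 random lists of the same size and mean level the median share was 27.3% and the highest 49.1%, a permutation p of 1e-04, the smallest they can give. Since the list was written after its members' changes had been seen, the permutation p bears on brightness only. It is not separate evidence of an effect on the family. Genes of a family are not independent, and cross-hybridization between family members was not tested, so an effect of inoculation on peroxidase genes is a hypothesis.

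Of 5 measured root hair markers, 4 were lower. A larger share of shoot tissue in the inoculated samples would raise the shoot markers while diluting root hair transcripts. This is argued against by the shoot markers' median change of -0.64, with all 4 changes below 0 by more than 2 SE and 3 of 4 past the threshold. The argument holds only if inoculation did not itself lower the shoot marker transcripts, which was not tested. A loss of root hair cells and a lower expression per cell cannot be told apart. Fewer cells alone would lower all markers alike, if their transcripts were found in root hairs only. The changes differed by 2.98 on the log2 scale: PER7 fell by 2.75 ± 0.13 (SE), EXPA18 by 2.22 ± 0.10, EXPA7 by 1.71 ± 0.15 and SCN1 by 0.51 ± 0.10, while XTH26 differed by 0.23 ± 0.11 (adjusted p = 0.192). Transcripts of SCN1 in other root cells were not measured, and XTH26 had a mean level of only 3.75 in mock roots, so the unequal changes leave both explanations open. Which cells carry the other expansin and XTH transcripts is not in these data, so no such explanation was tested for them.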
